A study of Homo sapiens with 6 samples.

How the data were processed

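Bulk RNA-seq of 2 human breast cancer cell lines was examined: parental MDA-MB-231 (3 libraries) and MDA-MB-231-D3H2LN, abbreviated MDA231-LN (3 libraries). Per the labels, both were kept in high-glucose DMEM with 10% serum, RNA was isolated with a column kit, and total RNA was sequenced by a service provider as read pairs of 150 bases. Per the labels the reads were aligned to GRCh38 with STAR, whose version is not given. The deposited table holds raw counts per gene for 61541 genes, which the authors made, per the file headers, with featureCounts 2.0.1 on Ensembl annotation release 105. Per the file headers these counts cover whole gene bodies, introns included, ignore the strand, and leave out reads that touch more than 1 gene or align to more than 1 place. The labels also name DESeq2, whose output is not used here.

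Samples were grouped by cell line as the labels give it, and the contrast was MDA231-LN minus parental. Gene symbols were found for 61369 genes (99.7%), and biotypes came from GENCODE 29 for 58366. Counted fragments came to 16831047, 16461578 and 19171017 in the parental libraries and 18843076, 17661542 and 18882719 in MDA231-LN. A floor of 3 counts over the 3 libraries of a line corresponds to 0.059 CPM in the parental line and 0.0526 CPM in MDA231-LN, on the TMM-scaled library sizes used for all CPM values. Where a line had 0 counts the fold is a lower bound against that floor, and with 1 to 3 counts a ratio of counts over the same library sizes is given with an exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

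Genes were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 after TMM scaling and filterByExpr, which kept 14176 genes, with Benjamini-Hochberg adjustment over them. A gene passed at an adjusted p under 0.05, and counts at an absolute log2 fold change of at least 1 are given beside. The common biological coefficient of variation was 0.0691. Of 31 gene lists, those with at least 5 tested members (29) were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over these lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. Shifts of whole chromosomes were tested with a two-sided permutation test of the mean log2 fold change, with 100000 resamples, adjusted over 24 chromosomes; genes are not independent replicates, so this describes the libraries.

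The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names JAG1 with every Notch ligand and receptor. It names in each direction the 12 genes with the largest absolute log2 fold change among those with a conventional symbol, protein coding where a biotype was at hand, that passed with a mean CPM of at least 5 and no overlap between the lines. From each list it names up to 4 members with the smallest adjusted p among those past the threshold and changed at least 2-fold, or otherwise up to 2 with the smallest adjusted p. IRX2-DT entered by this rule. Some genes that the rule names are not reported here.

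Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, glmTreat against 1.5-fold, camera with an estimated correlation, fry, and the median in place of the mean for chromosomes. Chosen after seeing the data were leaving out genes with over 50% of their exonic bases inside another gene, and subtracting the median of each 10-Mb window. Tested on simulated data of 14176 genes with 3 libraries per group, edgeR recovered 24.1% of genes changed 1.2-fold and 58.1% at 1.5-fold. It recovered 77.8% at 2-fold and 88.9% at 4-fold, and called 9 unchanged genes. Only 58, 43, 54 and 45 genes were changed at these folds, independently of each other. In the real data 62.8% of the tested genes passed, so these rates may not carry over to them. On simulated data camera called a list raised 1.5-fold. Of 200 unchanged lists, 2 had an unadjusted p under 0.05. These lists were random genes simulated independently, so they do not test shifts shared by neighbouring genes. A shift of 0.3 added to chromosome 4 after shuffling was found, with 0 other chromosomes called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

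Because reads touching more than 1 gene are left out, genes lying inside another annotated gene can be listed with few or no counts while expressed; 38748 genes share part of their span with another. The share of exonic bases inside another gene is given beside named genes where it is large, and such genes without counts are reported as not measured. No library was left out.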

Results

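RNA from 2 human breast cancer cell lines was sequenced: parental MDA-MB-231, a triple-negative line from a metastatic adenocarcinoma, and MDA-MB-231-D3H2LN, called MDA231-LN here, known as a luciferase-carrying subline recovered from a lymph node metastasis in mice. Each line was represented by 3 bulk RNA-seq libraries of total RNA from cells grown in the same medium with 10% serum. The libraries held 16461578 to 19171017 counted fragments in the parental line and 17661542 to 18882719 in MDA231-LN. Between 17962 and 18196 genes had a count in the parental libraries and between 19839 and 20024 in the MDA231-LN libraries. The first principal component of log2 CPM (counts scaled to a common library size) separated the lines and carried 86.5% of the variance. Library pairs within a line differed beyond sampling noise, with a chi-square per degree of freedom of 3.86 to 9.07, so none was a second sequencing of the same library; pairs from different lines gave 93.2 to 109. Nothing in the labels says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

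The series asks, by its title, about JAGGED-1 in tumor cells and lymph node metastasis. The comparison shows which genes differ between the parental line and this lymph-node-derived subline. Each kind of cell is represented by a single line. Lymph node origin therefore cannot be told apart from the luciferase, the growth in mice or any other difference between the lines. JAG1, which encodes the Notch ligand JAGGED-1, was slightly higher in MDA231-LN: 184 ± 2.76 CPM in the parental line and 213 ± 6.76 CPM in MDA231-LN (SD, n = 3), a 1.16-fold difference with log2 fold change 0.21 ± 0.05 (SE). This passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.00155), and all 3 MDA231-LN libraries lay above all 3 parental libraries. The ligand genes JAG2 and DLL1 moved further. JAG2 rose 7.42-fold, from 4.42 ± 0.639 to 32.7 ± 3.41 CPM (log2 fold change 2.89 ± 0.14). DLL1 had 3 counts over the 3 parental libraries and 254 over the 3 MDA231-LN libraries, a ratio of 75.5 (95% counting interval 25.6 to 369). Values are given below in the order parental to MDA231-LN, with ± as the SD over the 3 libraries for CPM and the SE for log2 fold changes. The words "rose" and "fell" mean higher or lower in MDA231-LN at an adjusted p under 0.05. JAG1 lies on chromosome 20 from 10637684 to 10673999, JAG2 on chromosome 14 from 105140982 to 105168824 and DLL1 on chromosome 6 from 170282206 to 170306565 of GRCh38. Of their exonic bases 9.2%, 20.9% and 1.2% lie inside another annotated gene.

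**Figure D1:**
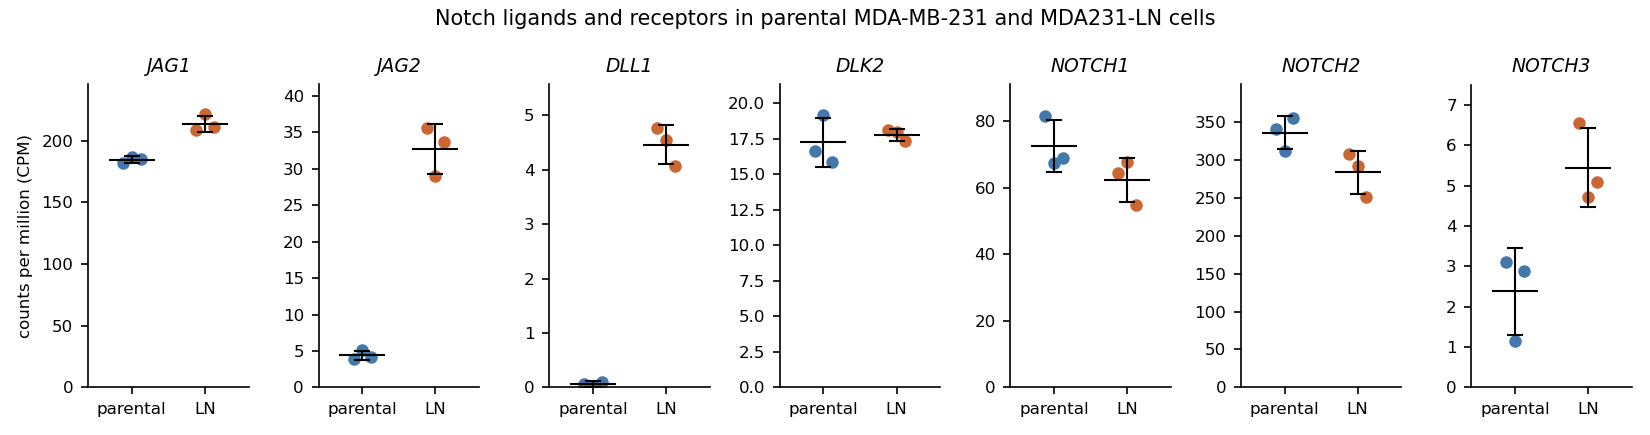
CPM (vertical axes, each from 0) of the 7 tested Notch ligand and receptor genes in the 3 parental (blue) and 3 MDA231-LN (orange) libraries; points are libraries, the wide bar is the mean and the whiskers are the SD. JAG1 differs by 1.16-fold, while JAG2 is 7.42-fold higher in MDA231-LN.

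Among the receptors, NOTCH3 rose 2.27-fold (2.38 ± 1.08 to 5.45 ± 0.975 CPM; log2 fold change 1.18 ± 0.28), whereas the more abundant NOTCH2 fell slightly (336 ± 21.9 to 284 ± 28.7 CPM; log2 fold change -0.25 ± 0.06). NOTCH1 also fell slightly (72.5 ± 7.74 to 62.2 ± 6.66 CPM; log2 fold change -0.22 ± 0.08), but its libraries overlapped between the lines. With upper-quartile scaling (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.276), DESeq2 (adjusted p = 0.061) or without parental replicate 1 (edgeR, adjusted p = 0.187) or MDA231-LN replicate 3 (adjusted p = 0.198) the call was lost. Over all alternatives the NOTCH1 log2 fold change had an adjusted p of 0.00907 to 0.276, and the NOTCH2 log2 fold change one of 3.25e-05 to 0.0817. NOTCH2 likewise lost its call with upper-quartile scaling (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0817). DLK2, a non-canonical ligand, was at 17.2 ± 1.74 to 17.8 ± 0.428 CPM and did not pass. Of the 11 ligand and receptor genes, 7 could be tested; 4 rose and 2 fell (4 and 2 adjusted over the list alone). DLL3, DLL4, NOTCH4 and DLK1 had too few counts. The list as a set did not stand apart from all genes (camera, Benjamini-Hochberg adjusted p = 0.341).

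Of 10 tested Notch target genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone). The risers at least 2-fold apart were low-abundance genes. They included HEYL (0.796 ± 0.377 to 2.91 ± 0.496 CPM) and HES7 (0.929 ± 0.275 to 3.26 ± 0.797 CPM), which encode transcriptional repressors of the Hes and Hey family. NRARP, a feedback inhibitor of Notch signalling (2.05 ± 1.39 to 5.43 ± 1.18 CPM), rose, as did BHLHE41 (1.17 ± 0.546 to 4.94 ± 0.956 CPM, with 47.9% of its exonic bases inside another gene). As a set the targets did not pass (camera, Benjamini-Hochberg adjusted p = 0.51). The processing and effector machinery of the pathway leaned the other way: of 22 tested genes 15 fell and 5 rose (15 and 5 adjusted over the list alone). NCSTN, a subunit of gamma-secretase, fell 2.43-fold (250.4 ± 14.3 to 103 ± 4.05 CPM), and the coactivator MAML2 fell 2.81-fold (49.6 ± 3.03 to 17.7 ± 1.44 CPM). Both lie in 10-Mb windows whose genes were lower as a whole (median log2 fold change -0.61 and -0.78). POGLUT1, which glycosylates Notch receptors, fell 2.18-fold (34 ± 1.97 to 15.6 ± 1.7 CPM). NEURL1, a ubiquitin ligase acting on Notch ligands, rose 4.79-fold from a low level (1.16 ± 0.594 to 5.52 ± 0.795 CPM). The set missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0732). It passed with no filter (camera adjusted p = 0.0114), without parental replicate 1 (0.0397), without overlapped genes (0.0343) and after subtracting window medians (0.0183), within a range of 9.04e-05 (fry) to 0.516 (estimated correlation).

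Differences between the lines extended over most of the expressed genes. Of 14176 genes tested, 8904 passed an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 4482 higher and 4422 lower in MDA231-LN. Of these, 2916 differed at least 2-fold, 1848 higher and 1068 lower, so that 63.4% of the larger differences were higher in MDA231-LN. Upper-quartile scaling moved the median log2 fold change of all tested genes from 0.02 to 0.13, and small differences are relative to that. With that scaling 60% of the genes past the threshold and 70.7% of those changed at least 2-fold were higher in MDA231-LN, against 50.3% and 63.4% as reported.

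The 12 largest increases were mostly genes with no counts at all in the parental line. NCAM1, a neural cell adhesion molecule, rose from 0 to 46.4 ± 2.28 CPM, at least 787.2-fold higher; folds against a line with 0 counts are lower bounds set against a floor of 3 counts over its 3 libraries. ACTG2, smooth muscle gamma-actin, reached 44.7 ± 1.87 CPM (at least 758.7-fold), and the homeobox gene IRX2 44.5 ± 4.07 CPM (at least 753.8-fold) together with its neighbour IRX2-DT at 12.6 ± 1.74 CPM (at least 213-fold). PDPN, which encodes podoplanin, a membrane glycoprotein of lymphatic endothelium and some tumor cells, reached 24.9 ± 0.232 CPM (at least 422.8-fold). MYH14, a non-muscle myosin heavy chain, VAT1L, the RNA-binding protein gene LIN28B, RFPL4AL1 and the presynaptic gene RIMBP2 were at 10.0 to 12.6 CPM in MDA231-LN and at 0 in the parental line, at least 170.3-fold to 212.9-fold higher. CADM1, another adhesion molecule, had 2 parental counts against 7449, a ratio of 3323 (95% counting interval 919.6 to 27440), and the potassium channel gene KCNQ3 had 1 against 1165, a ratio of 1039 (95% counting interval 186 to 41090). NCAM1 and CADM1 lie on chromosome 11 from 112961247 to 113278436 and chromosome 11 from 115169218 to 115504957, IRX2 on chromosome 5 from 2745845 to 2751677 and PDPN on chromosome 1 from 13583465 to 13617957. RFPL4AL1 and ACTG2 have close relatives in the genome, and reads that map equally well to such copies were not counted.

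**Figure D2:**
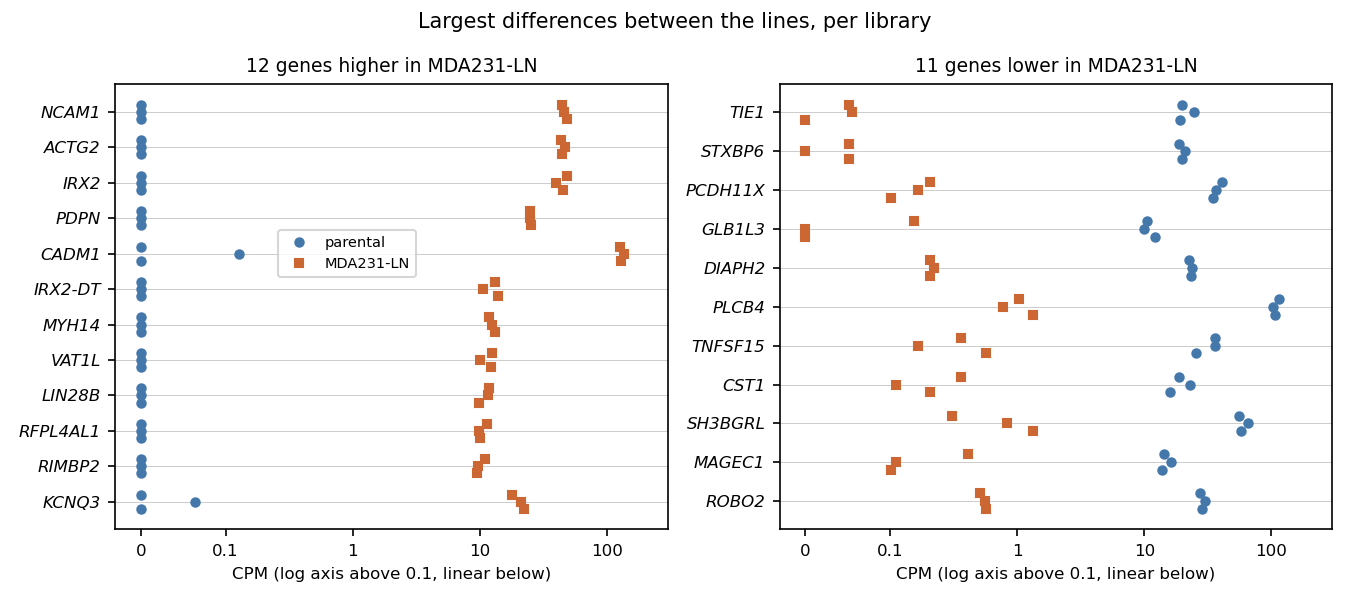
CPM per library (horizontal axis, linear below 0.1 and logarithmic above) of the 12 genes with the largest increase (left) and 11 of the 12 with the largest decrease (right) in MDA231-LN, as parental (circles) and MDA231-LN (squares) libraries. Most of the genes on the left are at 0 in all 3 parental libraries, and NCAM1 averages 46.4 CPM in MDA231-LN.

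Among the 12 largest decreases, TIE1, an endothelial receptor tyrosine kinase gene that the parental line expressed at 21.1 ± 3.02 CPM, had 1069 counts in the parental libraries against 2 in MDA231-LN, a ratio of 599 (95% counting interval 165 to 4953). STXBP6, a SNARE-binding protein gene, had 1009 against 2, a ratio of 566 (95% counting interval 156 to 4676), and GLB1L3 554 against 3, a ratio of 207 (95% counting interval 70.5 to 1007). PLCB4, a phospholipase C gene, fell 102-fold from 108 ± 6.08 CPM, and TNFSF15, a cytokine gene of the TNF superfamily, 86.8-fold (32.5 ± 6.15 to 0.363 ± 0.199 CPM). CST1, a secreted cysteine protease inhibitor, fell 82.3-fold (19.3 ± 3.54 to 0.225 ± 0.126 CPM), and ROBO2, a receptor for Slit guidance proteins, 51.8-fold (28.5 ± 1.49 to 0.544 ± 0.0263 CPM). Members of this group on the X chromosome included PCDH11X (227-fold lower), the formin gene DIAPH2 (106-fold lower, with 61.7% of its exonic bases inside another gene), SH3BGRL (71.4-fold lower) and the cancer-testis antigen gene MAGEC1 (67.8-fold lower). PCDH11X, DIAPH2 and SH3BGRL lie between 80 and 100 Mb of X, a region picked after the values were seen. There 13 of 16 tested genes fell, and 9 were at least 4-fold lower. TIE1 lies on chromosome 1 from 43300982 to 43323108 and PLCB4 on chromosome 20 from 9067825 to 9504593. CST1, MAGEC1 and PCDH11X belong to families with close copies, and reads that align equally well to such copies were not counted.

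Mesenchymal genes were higher as a set. Of 20 tested, 11 rose and 4 fell (11 and 4 adjusted over the list alone), and 9 of the risers rose at least 2-fold. COL6A1 and COL6A2, which encode chains of collagen VI, rose 10.8-fold (41.7 ± 4.16 to 448 ± 21.7 CPM) and 14.1-fold (13.2 ± 2.73 to 185 ± 2.76 CPM). The cadherin gene CDH11 rose 28.1-fold (2.59 ± 0.156 to 73.1 ± 0.717 CPM) and SPARC, a secreted matrix glycoprotein, 37.2-fold (1.15 ± 0.213 to 42.7 ± 1.83 CPM). The set passed (camera, Benjamini-Hochberg adjusted p = 0.0323), with adjusted p = 0.516 with an estimated correlation and 1.61e-05 with fry as the ends of its range. Upper-quartile scaling (camera adjusted p = 0.0525) and leaving out MDA231-LN replicate 3 (camera adjusted p = 0.0511) also ended the call. Epithelial genes went both ways: of 15 tested, 4 rose and 8 fell (4 and 9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.383). The splicing regulators of the epithelial state moved apart, ESRP1 rising 39.1-fold from near 0 (0.103 ± 0.0937 to 4.12 ± 0.866 CPM) and ESRP2 falling 4.07-fold (11.3 ± 1.02 to 2.75 ± 1.4 CPM). SPINT1, a membrane serine protease inhibitor, rose 6.54-fold (1.55 ± 0.416 to 10.1 ± 0.663 CPM), and the tight junction gene CLDN7 fell 4.29-fold (8.47 ± 1.61 to 1.97 ± 0.524 CPM, 52.7% of its exonic bases inside another gene). The median log2 fold change of the epithelial list was -0.34 and its mean 0.19, so these summaries differ in sign.

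Matrix genes were extensively exchanged between the lines. Of 29 tested matrix components, 16 rose and 11 fell (17 and 11 adjusted over the list alone), 13 and 5 of them at least 2-fold (camera, Benjamini-Hochberg adjusted p = 0.202). Collagen VI was among the risers, while COL8A1, a collagen VIII chain, fell 6.47-fold (434 ± 14 to 67.1 ± 0.606 CPM). Matrix proteases and their inhibitors were split, 10 rising and 9 falling of 20 tested (11 and 9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.823). Of this list, the membrane-type protease gene MMP14 fell 2.64-fold (1191 ± 81.8 to 452 ± 18.9 CPM) and the tissue plasminogen activator gene PLAT 3.42-fold (671 ± 74 to 196 ± 6.7 CPM). The inhibitor gene TIMP2 fell 2.30-fold (711 ± 13.5 to 309 ± 14.7 CPM). MMP1, PLAU and TIMP1, which belong to the same list, could not be measured: at least 93.8% of their exonic bases lie inside another gene, and they were listed with 0, 15 and 0 counts over all libraries. Of 26 tested integrins and adhesion molecules, 11 rose and 11 fell, or 12 and 9 with upper-quartile scaling (11 and 12 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.797). NCAM1 and CADM1 were among the risers, as was the integrin gene ITGB4 (46.2 ± 2.27 to 156 ± 7.44 CPM). The endothelial and melanoma adhesion molecule gene MCAM fell 17.8-fold (70.8 ± 5.03 to 3.98 ± 0.782 CPM, 57.3% of its exonic bases inside another gene).

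Angiogenic and lymphangiogenic factors rose more often than they fell, 12 against 4 of 19 tested (12 and 4 adjusted over the list alone), with no call for the set (camera, Benjamini-Hochberg adjusted p = 0.0971). ANGPT1, an angiopoietin gene, rose 2.82-fold (1.67 ± 0.251 to 4.72 ± 0.331 CPM). FLT4, the receptor for lymphangiogenic VEGF ligands, had 2 parental counts, and the ratio of counts was 20.5 (95% counting interval 5.37 to 174). THBS2, an inhibitor of angiogenesis, rose 58.9-fold (0.23 ± 0.158 to 14.3 ± 2.02 CPM, 80.7% of its exonic bases inside another gene), and SEMA3F, a repulsive guidance factor for lymphatic endothelium, fell 7.30-fold (39.7 ± 3.19 to 5.42 ± 0.705 CPM). VEGFC, given as an example that did not pass, was at 21.2 ± 3.1 to 24.9 ± 1.08 CPM. Chemokines and cytokines were mixed, with 8 rising and 5 falling of 20 tested (9 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.823). CSF1, the macrophage growth factor, fell 4.34-fold (184 ± 17.8 to 42.4 ± 0.962 CPM), IL11 3.07-fold (174 ± 13.7 to 56.4 ± 3.79 CPM), and IL24 3.12-fold (13.6 ± 2.94 to 4.34 ± 0.429 CPM, 41.6% of its exonic bases inside another gene). The granulocyte-macrophage factor gene CSF2 rose 5.60-fold from a low level (1.05 ± 0.295 to 5.89 ± 0.279 CPM). Of 15 chemokine receptors only 2 could be tested, too few for a set test. CCR7, a receptor for lymph node homing chemokines, rose 2.34-fold at a low level (0.874 ± 0.232 to 2.04 ± 0.336 CPM), and CXCR4, named after its value was seen, fell (9.84 ± 1.4 to 6.63 ± 0.537 CPM). Both kept their call adjusted over the list alone.

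Interferon-stimulated genes rose in 14 and fell in 8 of 30 tested cases (14 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.383). The antiviral genes OASL (1.44 ± 0.47 to 8.08 ± 1.37 CPM) and BST2 (3.37 ± 0.244 to 12.5 ± 1.24 CPM) rose, RSAD2 rose from 0 to 2.91 ± 1.08 CPM (at least 49.28-fold), and PARP14 fell 2.81-fold (48.6 ± 1.16 to 17.3 ± 2.35 CPM). A further 12 members, among them the IFIT and OAS genes, have over 90% of their exonic bases inside another gene. Among 15 tested genes of MHC class I presentation 3 rose and 5 fell, or 4 and 4 with upper-quartile scaling (3 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.636). HLA-B rose 2.23-fold (155 ± 13.9 to 346 ± 9.79 CPM), HLA-F 5.36-fold (0.305 ± 0.155 to 1.7 ± 0.0677 CPM, 62.9% of its exonic bases inside another gene). The peptide-trimming enzyme gene ERAP1 fell 2.28-fold (56 ± 3.79 to 24.6 ± 1.18 CPM, 65.4%). Class II genes rose in 5 and fell in 3 of 10 tested (6 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.383). The antigen-presenting chains HLA-DRA, HLA-DRB1 and HLA-DPB1 rose 8.63-fold (7.52 ± 0.546 to 64.8 ± 3.24 CPM), 5.17-fold (2.63 ± 0.376 to 13.6 ± 1.26 CPM) and 6.23-fold (0.612 ± 0.157 to 3.83 ± 1.14 CPM). In contrast CTSS, a protease that prepares class II molecules for peptide loading, fell 9.62-fold (5.81 ± 0.491 to 0.598 ± 0.0782 CPM). HLA genes are variable and similar to each other, so part of their reads may be lost or shared.

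Genes of cholesterol biosynthesis were lower as a set. Of 22 tested, 16 fell and 2 rose, or 14 and 4 with upper-quartile scaling (16 and 2 adjusted over the list alone), with a median log2 fold change of -0.46. The pathway enzymes PMVK, HSD17B7 and FDPS fell 2.46-fold (46.8 ± 3.3 to 19.1 ± 3.18 CPM), 2.32-fold (31.6 ± 1.42 to 13.6 ± 2.29 CPM) and 2.05-fold (113 ± 1.96 to 55.4 ± 4.29 CPM). All 3 lie on chromosome 1 in 10-Mb windows whose genes were lower as a whole, with median log2 fold changes of -0.97 (PMVK and FDPS) and -0.61 (HSD17B7). HMGCS1, named after its value was seen, was among the risers (61.1 ± 2.25 to 72.9 ± 1.64 CPM). The set passed (camera, Benjamini-Hochberg adjusted p = 0.00603), with adjusted p = 0.516 with an estimated correlation. After subtracting window medians the set median was -0.21 (camera adjusted p = 0.0372), within a range over the alternatives of 0.000103 (fry) to 0.516. Genes of the unfolded protein and amino acid stress response fell in 15 and rose in 4 of 26 tested, or 13 and 7 with upper-quartile scaling (15 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0953). They included the mTOR inhibitor gene DDIT4 (3.60-fold lower, 300.3 ± 31.4 to 83.4 ± 5.23 CPM) and the amino acid transporter gene SLC7A5 (2.41-fold lower, 1069 ± 3.44 to 443 ± 7.83 CPM). The chaperone gene HYOU1 fell 2.33-fold (390.5 ± 8.57 to 168 ± 5.56 CPM) and TRIB3 2.98-fold (57.8 ± 2.07 to 19.4 ± 1.03 CPM). HYOU1 lies in a 10-Mb window whose genes were lower as a whole (median log2 fold change -0.89).

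Hypoxia and glycolysis genes rose in 14 and fell in 8 of 29 tested (14 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.51). Of these EGLN3, an oxygen sensor, rose 3.49-fold (4.89 ± 1.47 to 17 ± 0.392 CPM) and CA9, a carbonic anhydrase, went from 3 to 183 counts, a ratio of 54.4 (95% counting interval 18.3 to 266). All 35 cell cycle genes could be tested; 17 rose and 5 fell (17 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0953), mostly by small amounts. With upper-quartile scaling 25 rose and 2 fell and the set passed (camera adjusted p = 0.0466), within a range over the alternatives of 0.00113 (fry) to 0.626 (estimated correlation). The cyclin gene CCNE1 was the only member past the threshold that differed at least 2-fold (12.5 ± 0.62 to 44.6 ± 4.65 CPM). Of 16 tested replication-dependent histone genes 9 rose and the other 7 did not pass (9 rose adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0953). They included H3C2 (0.83 ± 0.403 to 2.59 ± 0.337 CPM), H2AC20 (2.01 ± 0.599 to 4.45 ± 0.788 CPM), H2BC4 (1.19 ± 0.404 to 3.1 ± 0.592 CPM) and H3C3 (1.2 ± 0.478 to 2.96 ± 0.217 CPM). These genes are near copies of each other. The 13 protein genes of the mitochondrial genome moved unevenly, 4 rising and 6 falling, or 4 and 3 with upper-quartile scaling (4 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.771). MT-CYB rose 1.61-fold (2007 ± 134 to 3236 ± 175 CPM) and MT-CO1 fell 1.57-fold (15620 ± 776 to 9929 ± 684 CPM).

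TGF-beta target genes rose in 11 and fell in 7 of 21 tested (11 and 7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.383). LTBP1, which binds latent TGF-beta, rose 6.04-fold (32.2 ± 2.13 to 195 ± 4.4 CPM), TGFBI 3.33-fold (94.5 ± 5.03 to 315 ± 6.61 CPM) and PMEPA1, a feedback inhibitor, 2.86-fold (84.7 ± 2.1 to 242 ± 8.73 CPM). YAP and TAZ targets fell in 13 and rose in 4 of 23 tested, or 10 and 6 with upper-quartile scaling (13 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0953). They included CRIM1 (2.84-fold lower, 443 ± 1.92 to 156 ± 9.53 CPM, 46.3% of its exonic bases inside another gene). WWC1 was 2.19-fold lower (129.9 ± 3.08 to 59.2 ± 2.48 CPM) and ARHGEF17 2.32-fold lower (68.5 ± 3.69 to 29.5 ± 1.92 CPM). The log2 fold change of ARHGEF17 (-1.21) was smaller in size than the median of its 10-Mb window (-1.48), so it fell less than its region. NF-kappa-B targets rose in 5 and fell in 7 of 21 tested, or 8 and 6 with upper-quartile scaling (5 and 7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.663). The inhibitor gene NFKBIA fell 3.11-fold (89.5 ± 17.3 to 28.8 ± 2.43 CPM) and TNFAIP2 2.14-fold (201 ± 6.66 to 94 ± 1.46 CPM). BIRC3, an inhibitor of apoptosis, fell 3.45-fold (7.71 ± 0.536 to 2.23 ± 0.226 CPM, 55.8% of its exonic bases inside another gene). Its 10-Mb window had a median log2 fold change of -0.98. By contrast the cyclooxygenase gene PTGS2 rose 6.24-fold (1.53 ± 0.385 to 9.53 ± 1.07 CPM).

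Genes known from lung-metastatic sublines of MDA-MB-231 were higher in MDA231-LN. Of 13 tested, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 fold change of 1.32. EREG, a ligand of the EGF receptor, rose 26.8-fold (1.68 ± 0.485 to 44.6 ± 0.829 CPM), and SPARC, LTBP1 and PTGS2 are also members. The 2 that fell, MMP2 (1.27 ± 0.136 to 0.0355 ± 0.0309 CPM) and PLAAT4 (5.07 ± 0.631 to 1.7 ± 0.0149 CPM), are named after their values were seen. The list does not record in which direction each gene differs in those sublines, so a fall need not run against them. The set passed (camera, Benjamini-Hochberg adjusted p = 0.0313), with adjusted p = 0.516 with an estimated correlation and camera adjusted p = 0.0525 with upper-quartile scaling, within a range of 3.08e-05 (fry) to 0.516. The list of bone-metastatic sublines, which contains JAG1, fell in 5 and rose in 2 of 8 tested (5 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0971). IL11 and the activin antagonist gene FST (182 ± 9.14 to 88.6 ± 2.37 CPM) fell at least 2-fold. MMP1 belongs to both lists and could not be measured.

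**Figure D3:**
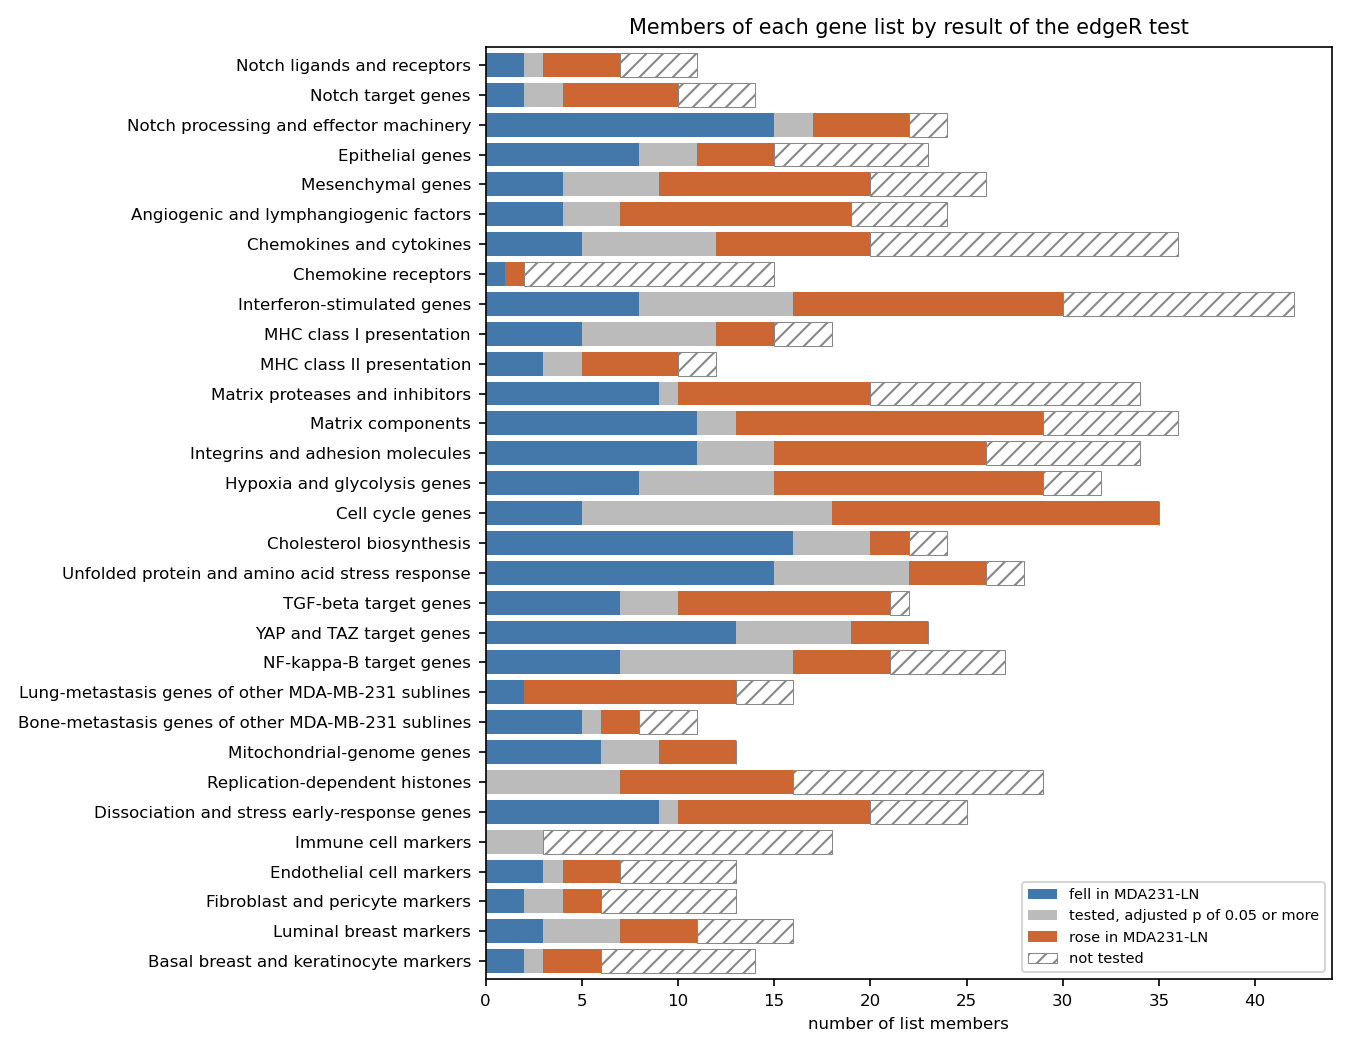
Number of members (horizontal axis) of each of the 31 gene lists that fell (blue), rose (orange) or did not pass (grey) in MDA231-LN against the parental line, and members not tested (hatched). In cholesterol biosynthesis 16 of 22 tested genes fell, and in the lung-metastasis list 11 of 13 rose.

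Markers of other cell types gave no uniform shift. Of 18 immune markers 3 could be tested and 0 passed by edgeR, with 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 by DESeq2 and 1 with upper-quartile scaling. CSF1R was at 1.48 ± 0.25 to 2.46 ± 0.734 CPM and CD8A at 4.64 ± 0.471 to 3.83 ± 0.727 CPM. Endothelial markers rose in 3 and fell in 3 of 7 tested, or 3 and 1 with DESeq2 (3 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.771). PDPN and FLT4 rose, as did PROX1, a lymphatic transcription factor gene, 20.4-fold at a low level (0.183 ± 0.126 to 3.76 ± 0.77 CPM), while TIE1 fell. Fibroblast and pericyte markers rose in 2 and fell in 2 of 6 tested (3 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.797). COL3A1 went from 1 to 88 counts, a ratio of 78.5 (95% counting interval 13.7 to 3136), and LUM from 1 to 47, a ratio of 41.9 (95% counting interval 7.17 to 1691). PDGFRB fell 2.31-fold (6.68 ± 1.9 to 2.88 ± 0.401 CPM). Luminal breast markers rose in 4 and fell in 3 of 11 tested (4 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.96). FOXA1 (0.179 ± 0.0677 to 2.63 ± 0.841 CPM) and MUC1 (0.743 ± 0.429 to 2.93 ± 0.615 CPM) rose from low levels, and the receptor gene ERBB3 (6.09 ± 0.698 to 2.24 ± 0.323 CPM) fell. Basal and keratinocyte markers rose in 3 and fell in 2 of 6 tested (3 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.51). ITGB4 rose and KRT17 went from 1 to 64 counts, a ratio of 57.1 (95% counting interval 9.89 to 2290.0). Early-response genes of cell dissociation and stress rose in 10 and fell in 9 of 20 tested, or 11 and 5 with upper-quartile scaling (10 and 9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.722). JUND fell 2.58-fold (164 ± 19 to 63.5 ± 6.25 CPM) and the heat shock gene HSPA1A, a near copy of HSPA1B, 5.26-fold (20.4 ± 0.804 to 3.86 ± 1.09 CPM). By contrast HSPB1 rose 2.06-fold (115 ± 10.6 to 237 ± 5.0 CPM) and BTG2 10.7-fold from a low level (0.262 ± 0.111 to 2.83 ± 0.828 CPM). In the endothelial, luminal, NF-kappa-B and class I lists the median, mean and direction of the set test did not all have the same sign, and none of these sets was called.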

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

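Leaving out genes with over 50% of their exonic bases inside another gene, and subtracting the median of each 10-Mb window, were chosen after the results were seen; the other alternatives were planned. JAG1 expression kept its direction and stayed past the threshold of 0.05 under the other scalings, filters and tests of a difference, with the block, with each library left out and without overlapped genes, with a log2 fold change of 0.18 to 0.32 and an adjusted p of 1.1e-05 to 0.0195. Minus its window median it was 0.38, a value with no test. The genes past the threshold numbered 8262 to 9361 over the fits at the same threshold of 0.05 on all genes (8904 as reported), 7583 at an adjusted p under 0.01 and 8195 without overlapped genes. Those changed at least 2-fold numbered 2518 to 3495 (2916 as reported), 2604 without overlapped genes and 2394 after subtracting window medians. With glmTreat against 1.5-fold in place of the 2-fold bound, 3469 genes passed, 1935 higher and 1534 lower. With the replicate number as a block, 8591 and 2833 genes passed and JAG1 had a log2 fold change of 0.21 (edgeR, adjusted p = 0.00426). Residuals of libraries with the same number correlated across genes at -0.004, 0.002 and -0.053, against -0.044 to 0.046 for different numbers. No effect shared by libraries of the same number was thus seen. Whether they were prepared together is not stated. The number of gene lists past the threshold was 3, and 7 with no filter, 0 with an estimated correlation (camera, with 2 at an unadjusted p under 0.05), 22 with fry, which does not compare a list with other genes, 2 to 4 when leaving out a library, and 5 after subtracting window medians, with Notch machinery (adjusted p = 0.0183) and unfolded protein and amino acid stress response (adjusted p = 0.0115) added. With no filter the added lists were Notch machinery, unfolded protein and amino acid stress response (adjusted p = 0.0198), YAP and TAZ targets (adjusted p = 0.0198) and replication-dependent histones (adjusted p = 0.0329). The number of chromosomes past the threshold was 7 by the mean, 12 by the median and 6 with 1 CPM in 3 libraries, where chromosome 15 no longer passed. Of 1628 values of 117 named genes under alternatives, 1620 kept their side. NOTCH1 and NOTCH2 account for 5 that no longer passed, CSF1R for 2 that newly passed (0.84 with upper-quartile scaling, 0.90 without MDA231-LN replicate 1), and DLK2, which did not pass, reversed without parental replicate 3 (-0.016 to 0.12 when leaving out a library). Lists not past the threshold reversed the direction of their set test as follows, given by their median log2 fold change. With upper-quartile scaling these were chemokines and cytokines (0.51), matrix proteases (0.38) and luminal markers (0.10). With no filter these were the same lists (0.39, -0.078 and 0.10). With 1 CPM in 3 libraries they were chemokines and cytokines (-0.064) and fibroblast markers (0.077), and with fry chemokines and cytokines (0.39) and luminal markers (-0.0087). Luminal markers also reversed with the replicate block (-0.0081), without parental replicate 1 and without MDA231-LN replicate 2 (-0.039 to 0.025 when leaving out a library). Matrix proteases reversed without parental replicate 3 (0.11 to 0.33) and without overlapped genes (0.21), and endothelial markers without parental replicate 2 (-0.34 to -0.047). The cause was not tested. At this depth a gene under 0.059 CPM in the parental line or 0.0526 CPM in MDA231-LN was under the floor of 3 counts over the line.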

Other observations

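The gene families here, the stretches along chromosomes, and the tests on held-out genes, library depth and other cells were chosen after the results were seen. The chromosome test, the GC and length test, the tests of copies for absent genes, the overlap test and the other splits were planned before their results.

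Homeobox genes of the Iroquois family, regulators of embryonic patterning, were all higher in MDA231-LN among the 4 tested. Besides IRX2, IRX5 went from 0.116 ± 0.0507 to 9.66 ± 0.721 CPM, IRX3 from 3.75 ± 0.641 to 25.5 ± 1.35 CPM and IRX1 from 0.295 ± 0.101 to 3.6 ± 0.677 CPM, the last with 61.1% of its exonic bases inside another gene. Of 32 tested genes for potassium channel subunits, 20 rose and 2 fell (23 and 2 with upper-quartile scaling, 19 and 2 with DESeq2). The risers included KCNK5 (1.39 ± 0.364 to 13.8 ± 0.669 CPM) and KCNH5, which rose from 0 to 4.82 ± 1.16 CPM, at least 81.7-fold. Collagen genes rose in 17 and fell in 7 of 27 tested (18 and 7 with upper-quartile scaling), and laminin genes in 7 and 4 of 11 (7 and 3 with upper-quartile scaling, 6 and 4 with DESeq2). S100 genes of the cluster on chromosome 1, which encode small calcium-binding proteins, fell in 6 of 7 tested under each scaling, among them S100A4 (399.9 ± 58.4 to 87.6 ± 13.7 CPM) and S100A6 (889.8 ± 201 to 362 ± 28.9 CPM). The 158 genes of its 10-Mb window had a median log2 fold change of -0.97, close to the median of the family (-0.97). Single members differed from it, since 3 fell and 1 rose at least 2-fold. In the same cluster S100A2 rose (27 ± 7.42 to 74.3 ± 9.16 CPM). The cancer-testis antigen genes MAGEA3 and MAGEA6 rose from 0 to 5.53 ± 0.568 and 5.28 ± 0.229 CPM, at least 93.7-fold and 89.6-fold. They are near copies of each other, so their reads cannot be assigned with certainty, and MAGEC1 of the same family fell. The mitochondrial ribosomal RNA genes MT-RNR1 and MT-RNR2 fell by 1.11 and 1.13 on the log2 scale. Zinc finger genes of chromosome 19 rose in 63 and fell in 2 of 103 tested beyond 30 Mb, and rose in 8 and fell in 20 of 49 before it (9 and 17 with upper-quartile scaling). Beyond 30 Mb their median of 0.55 was close to that of all genes there (0.58).

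By the planned permutation test, the mean log2 fold changes of chromosomes 4 (0.47 above the mean of all genes), 14 (0.25) and 19 (0.20) lay above that of all genes. Those of chromosomes 11 (-0.41), 3 (-0.25), X (-0.23) and 15 (-0.21) lay below it, with p = 1e-05, the smallest that 100000 permutations can give, for chromosomes 3, 4 and 11. Against 0 instead, the means of chromosomes 11, 3, X and 15 were -0.20, -0.03, -0.009 and 0.006. By the mean, the last 3 thus hardly differed between the lines, while their medians were -0.23, -0.22 and -0.12. With 1 CPM in 3 libraries chromosome 15 no longer passed (permutation test, adjusted p = 0.0516). Of 12 stretches of shifted genes, those with the most genes were 19 from 30 to 60 Mb (488 genes, median log2 fold change 0.58), 1 from 30 to 100 Mb (401 genes, 0.54), 11 from 70 to 140 Mb (302 genes, -0.98), 7 from 100 to 160 Mb (291 genes, 0.69), X from 60 to 160 Mb (281 genes, -0.69) and 1 from 140 to 170 Mb (273 genes, -0.83). The 25 genes in the 10-Mb window of JAG1 had a median of -0.17. Some named genes given above without a window value also lie in shifted windows. Among them are JAG2 (window median 0.57), HEYL (0.53), CTSS (-0.97) and MCAM (-0.89). Their own log2 fold changes were larger in size, at 2.89, 1.85, -3.27 and -4.15. Others, such as TIE1 (window median 0.52) and NCAM1 (-0.89), moved against their windows.

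Neighbouring genes thus shifted together, with log2 fold changes limited to an absolute value of 2 for this purpose. Of the variance of these values, 18.0% lay between 10-Mb windows, against at most 2.81% with shuffled positions (permutation p = 1e-05, the smallest possible). Of this variance 93.7% was left after removing trends on GC content, transcript length and level, which argues against these as the whole cause. In windows chosen on a random part of the genes, 82.3% of the held-out genes lay on the side of their window (50.3% with shuffled positions), as a difference in chromosome copies between the lines would need. That difference may be the source, but it remains a hypothesis, since no DNA was measured and regional regulation was not tested.

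With at most 3 counts over 1 line and at least 30 in each library of the other, 116 genes were absent from the parental line and 27 from MDA231-LN. Library depth is argued against, since the total counts of the lines differed 1.06-fold and these bounds would need 30-fold. Whether immune, endothelial or fibroblast cells in the MDA231-LN culture were the general source could not be decided. At most 42.9% of the tested markers rose in any of these lists (3 of 7 endothelial). This share cannot decide it, since the parental line itself expressed TIE1 (21.1 CPM), MCAM (70.8 CPM) and PDGFRB (6.68 CPM). A fall of such markers says nothing about other cells in MDA231-LN. Of 18 immune markers, moreover, only 3 were tested. Adjusted over the list alone or with upper-quartile scaling, 3 of 6 fibroblast markers rose. PTPRC, CDH5, DCN and COL1A2 had 56, 3, 2 and 27 counts over the 6 libraries. However, the endothelial risers PDPN, FLT4 and PROX1 are all lymphatic genes, against 3 endothelial markers that fell, and LYVE1 could not be measured. COL3A1 and LUM of the fibroblast list also rose, against 2 that fell. Such cells in the culture are therefore not excluded as a source. A difference in copies stays open: of the genes in windows with at least 15 tested genes, 3 of 18 absent from MDA231-LN (16.7%) lay in windows at or under -0.5 (Fisher's exact p = 0.442), and 19 of 113 absent from the parental line (16.8%) in windows at or over 0.5 (Fisher's exact p = 0.069), against 11.1% of the 13903 genes in windows in each case. It may account for part of these genes but cannot be told apart from other causes by these shares. A window median of 0.5 on the log2 scale is far smaller than the 30-fold difference that the bounds need. Loss of a single gene would not move a window median either. Of the 27 genes absent from MDA231-LN, 4 lay on X (Fisher's exact p = 0.0132), 3 of them between 80 and 100 Mb, which no window covered. PCDH11X, DIAPH2 and SH3BGRL of the largest changes also lie there. Of 10 other tested genes in this place, 7 were lower and 0 higher, with a median log2 fold change of -1.35 over the 10. This place was chosen after the values were seen, so these values are no test. Among the genes absent from the parental line was TTTY14, a lincRNA gene of chromosome Y, named after its value was seen. It had 3 parental counts against 167 in MDA231-LN. Chromosome Y was not part of the chromosome test, and the source of these counts was not tested.

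Some expressed genes were listed with few or no counts. Of 45 ribosomal, proteasome and respiratory-chain genes with over 90% of their exonic bases inside another gene, 42 (93.3%) had under 60 counts over the 6 libraries, against 7 of 124 (5.6%) with no overlap (Fisher's exact p = 1.02e-28, two-sided). The loss of reads that touch more than 1 gene may therefore hide such genes, among them MMP1, LDHB, TNC, SPP1 and JUNB, each listed with 0 counts. Biological silence of single genes of this kind was not tested and stays open for them.

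The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 8904 genes past the threshold and 2916 changed at least 2-fold by edgeR. The highest of the other splits gave 0 and 0, with at most 90 genes at an unadjusted p under 0.05. Thus 1 of the 10 splits gave counts as large. Every other split puts libraries of both lines in each group, which widens the spread within groups. Their 0 was therefore to be foreseen and is no measure of chance.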
